A study of Mus musculus with 11 samples.

How the data were processed

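CD45+ immune cells of C57BL/6 mice were profiled by CITE-seq, which reads the RNA and antibody tags of single cells together. The 4 groups were orthotopic lung tumours grown from LLC-Thy1.1 P2 cells (ORTHO-T), lung tissue adjacent to them (ORTHO-A), lungs of mice given buffer in place of cells (ORTHO-M) and subcutaneous tumours (SUBCUT). LLC-Thy1.1 is a mouse Lewis lung carcinoma line that carries the Thy1.1 surface marker, and P2 cells had been passaged in mice, per the labels, while P0 cells had not. Each group held 4 mice told apart by hashtag antibodies and was 1 capture, so capture and group were confounded. A biotinylated CD45 antibody given into the vein marked cells within reach of the blood, and streptavidin (STREP) tags read it out. Cultured P0 and P2 cells were profiled separately by 3′ RNA sequencing.

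Reads were processed with Cell Ranger against mm10, per the submitters' processing notes, and its version is not given in the sources used here. The deposited matrix of ORTHO-A held raw UMI counts of 32285 genes and 202 antibody features over 732787 barcodes, empty droplets included. Cell type names, mouse, group and the call of each cell as vascular or intratissue were category labels from the authors. How the authors filtered, clustered and named the cells and called them vascular is not given in the sources used here. A deposited doublet score, a fraction between 0 and 1 per cell, came with each cell, and its tool is not given in the sources used here. Count matrices of the other captures were not used here, so RNA and antibody levels were compared within ORTHO-A only. The rule fixed for naming cell types asked for an annotation of at most 20 types, and the coarsest one held 24 types, so all of these were used.

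Cells per type and mouse were compared with edgeR's quasi-likelihood test, with the cell total of the mouse as offset, all 4 groups in 1 fit and Benjamini-Hochberg adjustment over types. Types with at least 10 cells over the mice compared were tested. Each fold is the ratio of the mean shares of the 2 groups, and where a group held no cell of a type, it is a bound against 3 cells over the group, the smaller of the ratios from mean shares and from pooled cells. The share of cells called vascular was compared by an exact two-sided permutation test of 4 mice against 4, whose 70 arrangements give a smallest p of 0.0286. Per type, that test needed at least 10 cells in every mouse compared and was adjusted over types.

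For RNA, counts were summed per mouse and compartment within the 4 types with the most cells in the smaller compartment, of those with at least 20 cells in each compartment of at least 3 mice. Sums of at least 10 cells were kept. Vascular sums were set against intratissue sums with edgeR's quasi-likelihood test, TMM scaling, the filterByExpr filter and the mouse as a block. Both compartments came from the same mice, which is where that pairing comes from. Changes are log2 vascular minus intratissue with their standard errors and adjusted p-values, and levels are CPM, counts scaled to a total of 1e6 per sum, with SD over 4 mice. Antibody counts were fitted the same way for 193 antibodies, without hashtags and STREP tags. The 5 isotype controls and 2 CD45R antibodies were fitted and adjusted with the others and left out of the calls, which were made among 186. Of 34 fixed gene lists, those with at least 3 measured genes were tested by fry and by camera with an estimated correlation, both in limma, with adjustment over lists. Genes named were up to 10 per direction with adjusted p under 0.05, average log2 CPM of at least 5 and 1 direction in every mouse, leaving out variable segments and unnamed gene models, plus examples from the fixed lists. A called gene stays in all counts and is not reported here by name. Antibodies named were up to 8 per direction by the same rule without the level. Coordinates come from the GRCm38.p6 annotation, matched by symbol for 6366 of 6528 genes tested in neutrophils, 6807 of 6898 in alveolar macrophages, 1565 of 1601 in NK cells and 2165 of 2206 in B cells. Mitochondrial genes had no match there.

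Versions were edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The fits were tested on simulated data. At the depth of the neutrophil sums, 86% of genes changed 2-fold and 98% of genes changed 4-fold were recovered, among 6396 genes of which 200 changed, and 6.12% of calls were false. The same shares were 76%, 89% and 6.78% for alveolar macrophages over 6660 genes, 71%, 82% and 7.27% for NK cells over 1467 genes, and 55%, 79% and 5.63% for B cells over 2043 genes. For cell counts of ORTHO-A against ORTHO-M, 88.8% of types changed 4-fold were recovered over 40 runs, and 13.0% of unchanged types were also called.

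Groups, tests, gene lists and the naming rule were fixed before the data were examined. Alternatives fixed then were TMM on cell counts, limma on transformed shares, all types, cells called intratissue only, only the groups compared, a replicate block, equal weight of types, DESeq2, RLE size factors, no filter, no block, equal cells and totals, a stricter STREP call, antibody totals without TMM, and leaving out each mouse. Added after seeing the data were counts without neutrophils, counts without the NeuMono and DC3 types, cells with a doublet score under 0.5, and a label set on STREP per antibody count. For RNA and antibody tests, that label kept the number of vascular cells of each mouse and type. For vascular shares, it used a common cut for all types of a mouse, keeping the number of vascular cells of the mouse. Intervals and limits cover counting error only.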

Results

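The 4 captures held 49826 annotated immune cells, with 12313 in ORTHO-T, 12362 in ORTHO-A, 11898 in ORTHO-M and 13253 in SUBCUT. Cells per mouse ranged from 2158 to 4530, from 2407 to 4541, from 1677 to 3996 and from 1491 to 4393 in that order. In ORTHO-A the annotated cells held 40273095 gene UMIs and 40882932 antibody counts, with medians of 2434 UMIs and 962 genes per cell. Gene UMIs per ORTHO-A mouse were 6916329, 8236244, 7420694 and 17699828 for mice 1 to 4.

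The comparison of ORTHO-T with ORTHO-A asks how the immune cells of a lung tumour differ from those of the lung around it. Macrophages (Mph) made up 38.1% ± 5.15 of ORTHO-T cells and 2.04% ± 0.796 of ORTHO-A cells (SD, n = 4 each), 18.7-fold higher with an edgeR adjusted p of 1.61e-12. Immature macrophages (Immature Mph) were 86.4-fold higher, at 6.04% ± 1.57 against 0.0699% ± 0.0687 (adjusted p 1.24e-14). Neutrophils fell from 59.6% ± 3.37 in ORTHO-A to 25.5% ± 5.12 in ORTHO-T (adjusted p 0.00377). Alveolar macrophages (AM), the resident phagocytes of the airspaces, were 10.2-fold lower in tumours, at 1.11% ± 0.67 against 11.4% ± 2.15 (adjusted p 3.05e-09).

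Of 22 types tested, 15 differed between ORTHO-T and ORTHO-A, 11 higher and 4 lower in the tumour. Among dendritic cells, cDC2 were 5.01-fold, pDC 4.85-fold, DC3 4.53-fold and Mature DC 4.21-fold higher in ORTHO-T. Among lymphocytes, the type named Other T was 3.75-fold, regulatory T cells (Treg) 3.35-fold, Prolif NK/T 3.24-fold and CD8+ T cells 2.36-fold higher, the last at 4.79% ± 1.81 against 2.03% ± 1.02. B cells were 2.34-fold and the type named IM 6.44-fold lower. The B cell call was lost without ORTHO-A mouse 1 (log2 -0.91, adjusted p 0.0631), and pDC moved from a log2 ratio of 2.25 to 3.10 without ORTHO-A mouse 3. Of DC3 cells, 71.1% over all groups had a doublet score above 0.5, so these 25 cells of ORTHO-T and 7 of ORTHO-A are in doubt. NK cells stood at 5.53% ± 1.54 against 3.12% ± 0.821 with an adjusted p of 0.0497, and this call was lost with TMM scaling, among intratissue cells, with neutrophils left out and without any 1 of 5 mice. CD4+ T cells, cDC1, Prolif cDC, ILC2, NeuMono and both classes of monocytes (Class Mono and Non-class Mono) did not pass the test. Because shares of 1 mouse sum to 100%, the large neutrophil share weighs on every other type. With neutrophils left out of the total, 14 types differed, 6 higher and 8 lower in the tumour, and CD8+ T, DC3, Treg and Prolif NK/T no longer passed. Among intratissue cells alone, 13 types differed, 7 higher and 6 lower. The calls lost there were those of B cells (log2 -0.89, adjusted p 0.0873), DC3 (1.78, 0.0536), Mature DC (0.97, 0.0873), Treg (0.997, 0.103) and NK cells (0.65, 0.159). Class Mono (-1.36, 0.0071), Non-class Mono (-2.08, 0.00107) and ILC2 (-1.81, 0.00372) were lower there.

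**Figure D1:**
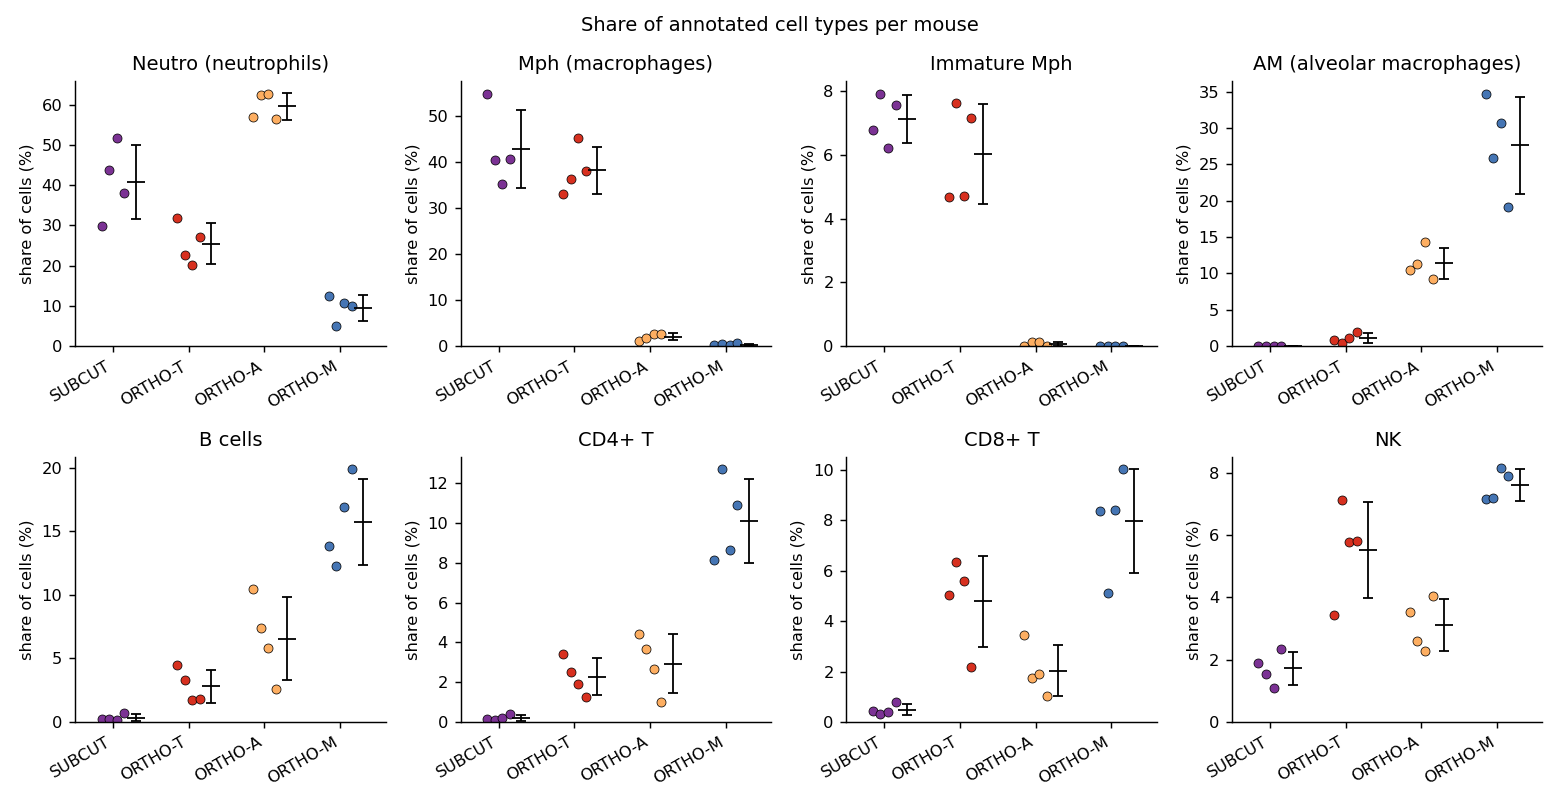
Share of 8 annotated types among all cells of a mouse, in percent, with a point per mouse and the mean and SD of each group. Macrophages reach 38.1% in ORTHO-T and 42.8% in SUBCUT against 2.04% in ORTHO-A and 0.369% in ORTHO-M, while alveolar macrophages go from 27.6% in ORTHO-M to 1.11% in ORTHO-T.

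The comparison of ORTHO-A with ORTHO-M asks what a tumour does to the lung around it. Neutrophils were 6.23-fold higher in ORTHO-A, at 59.6% ± 3.37 against 9.57% ± 3.27 of cells (SD, n = 4 each, edgeR adjusted p 1.87e-07). Mph were 5.53-fold higher, at 2.04% ± 0.796 against 0.369% ± 0.218 (adjusted p 1.13e-05), and NeuMono were 2.27-fold higher (adjusted p 0.0177), at 1.25% ± 1.02 against 0.551% ± 0.239. The NeuMono call rested on single mice: without ORTHO-A mouse 4 the log2 ratio went from 1.21 to 0.43 (adjusted p 0.407), without ORTHO-M mouse 4 to 0.97 (0.0829), and the exact permutation p was 0.143. Over all groups, 92.5% of NeuMono cells had a doublet score above 0.5. In all, 17 of 21 types differed, with these 3 higher and 14 lower in ORTHO-A, the lower ones including AM, at 11.4% against 27.6% ± 6.68, and B cells, at 6.57% against 15.7% ± 3.4.

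The 14 lower shares of ORTHO-A rested mainly on the neutrophils in the total. Among the remaining cells, with neutrophils left out, 4 types differed, 3 higher and 1 lower. Mph were higher by 3.61 (adjusted p 2.03e-08), NeuMono by 2.33 (0.000371) and Class Mono by 1.57 (0.00402) on the log2 scale. Group 2 innate lymphoid cells (ILC2) were the type lower there, with a log2 ratio of -1.33 (adjusted p 0.0308). AM, B cells and NK cells then stood at log2 ratios of -0.10, -0.09 and -0.14, and CD8+ T and CD4+ T cells at -0.83 and -0.61, with adjusted p of 0.867, 0.867, 0.818, 0.144 and 0.265. With TMM scaling of the cell counts, 5 types differed, 4 higher and 1 lower. Among intratissue cells alone, 10 differed, 3 higher and 7 lower, and CD4+ T (log2 -0.85), CD8+ T (-0.57), B (-0.56), NK (-0.46), Prolif NK/T (-0.37) and pDC (-0.30) no longer passed. The other shares lower in ORTHO-A over all cells were those of CD4+ T, CD8+ T, ILC2, IM, NK, pDC, cDC1, cDC2, Other T, Prolif cDC, Prolif NK/T and Plasma cells, the last with 1 cell against 11. The Prolif cDC call was lost without ORTHO-A mouse 1 (adjusted p 0.0612) or ORTHO-M mouse 4 (0.0756), and pDC moved from a log2 ratio of -2.33 to -3.18 without ORTHO-A mouse 3.

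**Figure D2:**
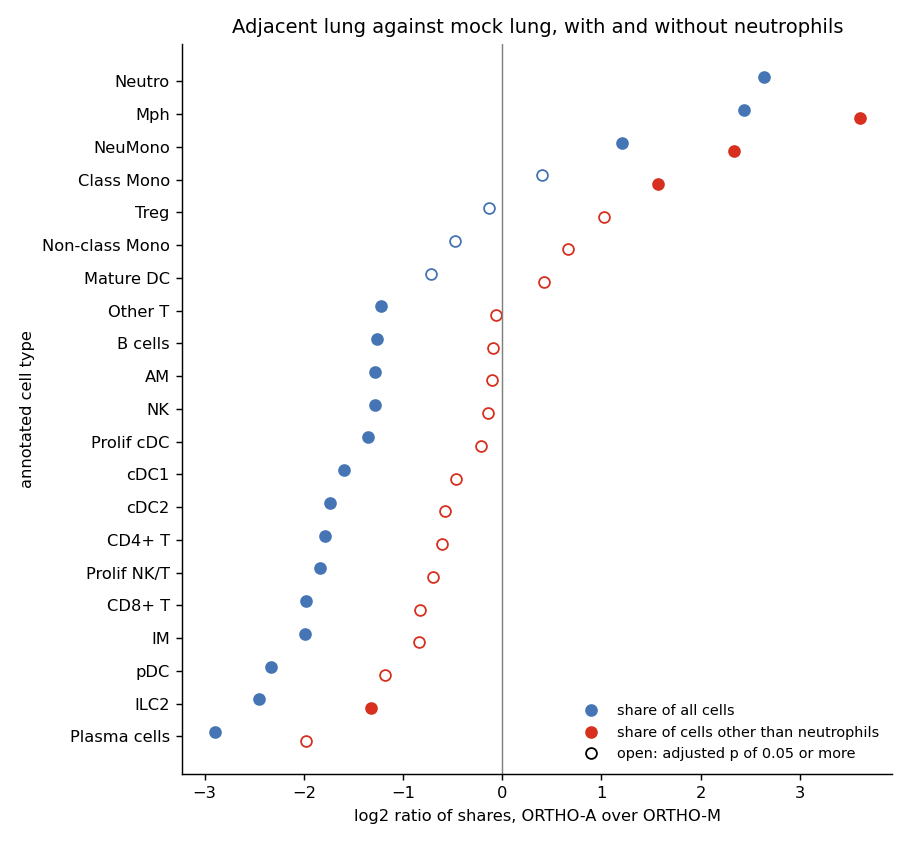
Log2 ratio of ORTHO-A over ORTHO-M for each type, as a share of all cells in blue and of cells other than neutrophils in red, where open marks stand for an adjusted p of 0.05 or more. Alveolar macrophages move from -1.28 in blue to -0.10 in red, and macrophages stay high in both.

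Against mock lungs, ORTHO-T showed the contrast of tumour with lung of mice without one. Mph were 103-fold higher in ORTHO-T than in ORTHO-M (edgeR adjusted p 9.84e-18). Immature Mph were at least 240-fold higher, with 764 cells in ORTHO-T and 0 of 11898 in ORTHO-M, which allows a share of up to 0.0252%. DC3, with 25 cells against 0, were at least 8.05-fold higher, and 71.1% of DC3 cells over all groups had a doublet score above 0.5. Neutrophils were 2.66-fold, Treg 3.25-fold and Mature DC 2.46-fold higher, the last call lost without ORTHO-T mouse 1 (adjusted p 0.142) and among intratissue cells (log2 0.60, adjusted p 0.284). AM were 24.8-fold, IM 25.8-fold, ILC2 10.6-fold, B cells 5.59-fold, CD4+ T cells 4.43-fold and cDC1 2.84-fold lower. Among intratissue cells the falls were smaller for B cells (log2 -1.46) and CD4+ T cells (-1.15). They were larger there for AM (-5.27), IM (-5.33), ILC2 (-4.14) and cDC1 (-2.25). Over all cells, the types named made 12 of 23, 6 higher and 6 lower. With TMM scaling 14 types differed, 9 higher and 5 lower, where 11 of the 12 calls were kept and that of cDC1 was lost (log2 -0.82, edgeR adjusted p 0.126). CD8+ T cells, at 4.79% against 7.98% ± 2.06, did not pass the test (log2 -0.74, adjusted p 0.118), and among intratissue cells the direction turned (0.84, 0.0819). Among intratissue cells 15 types differed, 7 higher and 8 lower, and Prolif NK/T turned from -0.23 (edgeR adjusted p 0.641) to 1.52 (0.0128).

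SUBCUT was set against ORTHO-T to compare tumours of 1 line at different sites. Mph made up 42.8% ± 8.4 of cells in SUBCUT and 38.1% ± 5.15 in ORTHO-T (SD, n = 4 each, edgeR adjusted p 0.699), and neutrophils 40.8% ± 9.21 and 25.5% ± 5.12. Lymphocytes were scarcer in SUBCUT, where CD8+ T cells fell to 0.484% ± 0.223 from 4.79% ± 1.81 (adjusted p 1.2e-08), and CD4+ T cells were 11.0-fold, B cells 8.20-fold and NK cells 3.21-fold lower. Treg did not follow, at 0.696% ± 0.262 against 0.685% ± 0.216 (adjusted p 0.983). Mast cells were found in SUBCUT, with 41 cells against 0 of 12313 in ORTHO-T, which allows a share of up to 0.0244%, and were at least 12.7-fold higher.

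In all, 17 of 23 types differed between SUBCUT and ORTHO-T, 2 higher and 15 lower in SUBCUT, and with TMM scaling 15 differed, 5 higher and 10 lower, with 12 of the 17 calls kept. The calls lost were those of NK (log2 -0.84), Mature DC (-0.80), Prolif NK/T (-0.71), cDC1 (-0.53) and Other T (-0.44), while neutrophils (1.42), Immature Mph (1.06) and Mph (1.01) then passed as higher. NeuMono was the other higher type, at 1.94% ± 0.369 against 0.923% ± 0.681 (adjusted p 0.0338, exact permutation p 0.0857), and that call was lost without any 1 of 6 mice. Without ORTHO-T mouse 4 its log2 ratio went from 1.04 to 1.74 (adjusted p 0.000704), and among intratissue cells it was 2.13 (7.3e-05). AM were at least 49.1-fold lower, with 0 of 13253 SUBCUT cells, which allows a share of up to 0.0226%. Non-class Mono were 10.8-fold, Class Mono 8.57-fold, pDC 5.43-fold, ILC2 5.15-fold, cDC2 3.42-fold, Mature DC 2.90-fold, Prolif NK/T 2.63-fold, cDC1 2.39-fold and Other T 2.32-fold lower. ORTHO-T mouse 4 carried much of the Non-class Mono value, which went from a log2 ratio of -3.63 to -2.33 (adjusted p 0.0139) without it. Prolif cDC went from 24 cells to 2. Neutrophils, at the shares above, and Immature Mph, at 7.13% ± 0.766 against 6.04% ± 1.57, did not pass the test (adjusted p 0.0886 and 0.607). Among intratissue cells alone neutrophils passed, with a log2 ratio of 1.01 (adjusted p 0.0204).

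The injected CD45 label asks which cells the blood could reach. In ORTHO-T, 16.9% ± 5.04 of cells were called vascular, against 56.1% ± 16.1 in ORTHO-A (SD, n = 4 each, exact permutation p = 0.0286). These shares also reflect the mix of types. With equal weight of types, they were 19.8% ± 2.50 and 47.7% ± 9.41 (exact permutation p = 0.0286). SUBCUT stood at 1.85% ± 1.18, below ORTHO-T (exact permutation p = 0.0286). ORTHO-M, at 52.7% ± 7.96, did not differ from ORTHO-A beyond the spread between mice (exact permutation p = 0.714). In ORTHO-A, the vascular share rose with the STREP counts of the mouse, as given below. Each group was 1 capture, so a difference in staining or in the cut could not be told from one between groups. CD8+ T cells were 13.9% ± 4.88 vascular in ORTHO-T and 59.4% ± 4.87 in ORTHO-A, and Mph 3.27% ± 2.05 and 35.4% ± 10.8.

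By type, 8 of 11 had a lower vascular share in ORTHO-T than in ORTHO-A, each with an exact permutation p of 0.0286, an adjusted p of 0.0393 and all 4 tumours below all 4 adjacent lungs. Besides CD8+ T cells and Mph, these were CD4+ T cells (22.9% against 61.6%), B cells (55.4% against 79.5%), cDC2 (3.73% against 21.6%), NeuMono (56.7% against 93.1%), Other T (4.43% against 20.4%) and AM (4.99% against 23.0%). Neutrophils (33.9% against 59.1%), NK cells (20.6% against 52.3%) and Class Mono (57.8% against 62.8%) did not pass, with adjusted p of 0.157, 0.0698 and 0.657. This test took the mice of ORTHO-T and ORTHO-A as independent. Were tumour and adjacent lung paired by mouse, which is uncertain, the smallest exact p would be 0.125. In that case no type could pass. Between ORTHO-A and ORTHO-M, 0 of 10 types passed the adjusted exact permutation test, and 1 had an unadjusted p under 0.05, CD8+ T cells at 59.4% against 84.0% ± 10.2 (exact p = 0.0286, adjusted p 0.286). Between SUBCUT and ORTHO-T, 0 of 9 types passed, and 3 had an unadjusted exact permutation p of 0.0286 with an adjusted p of 0.0857. Those were neutrophils (1.32% against 33.9%), NK cells (0.676% against 20.6%) and NeuMono (3.58% against 56.7%).

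**Figure D3:**
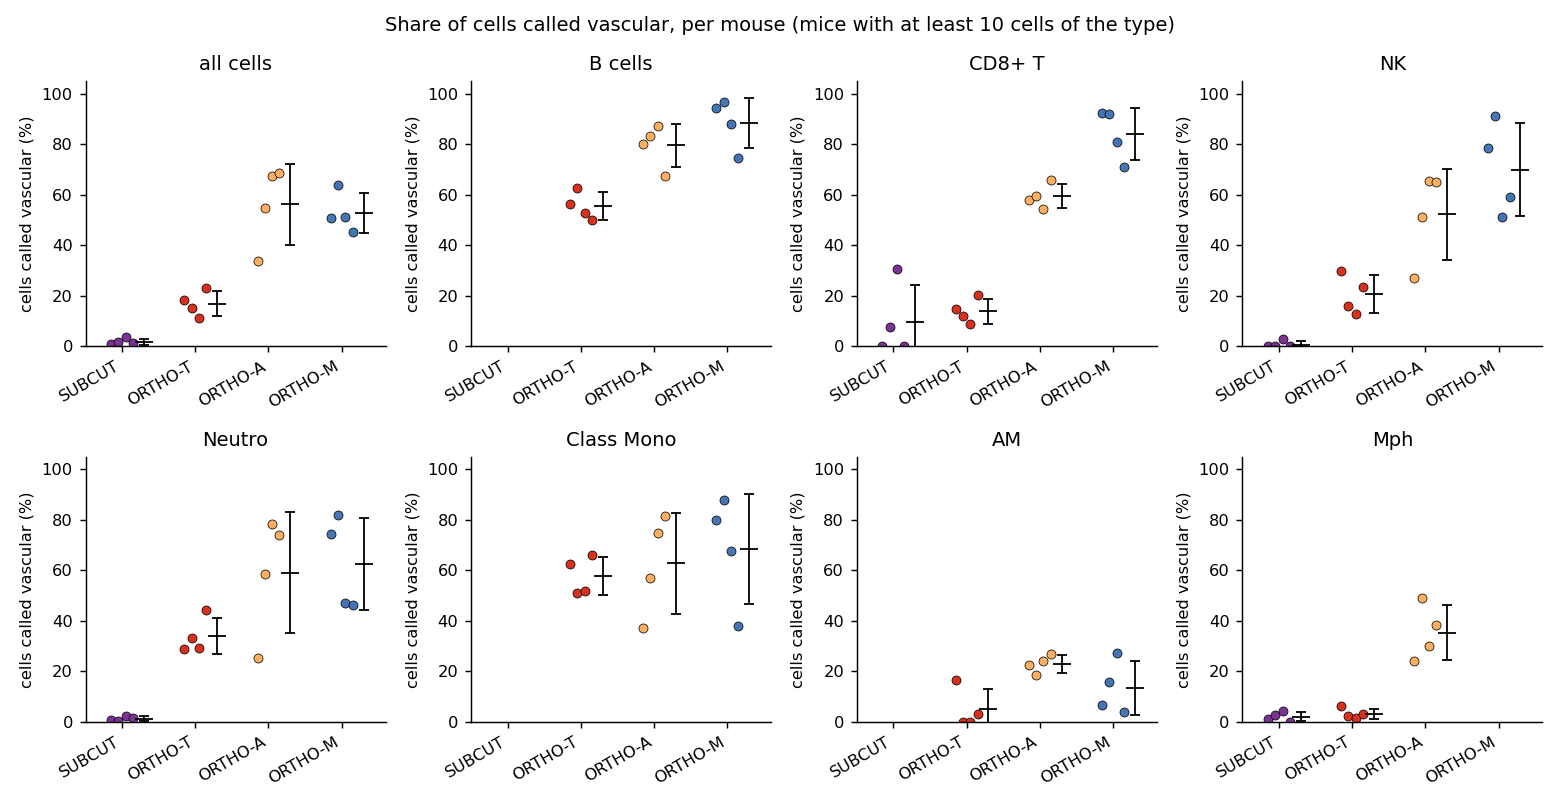
Percent of cells called vascular per mouse, for all cells and for 7 types, with a point per mouse and the mean and SD of each group, where mice with under 10 cells of a type are left out, and so are groups with fewer than 3 mice remaining. Shares of all cells run from 33.9% to 68.6% in ORTHO-A, from 11.1% to 22.9% in ORTHO-T and from 1.02% to 3.58% in SUBCUT.

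Within ORTHO-A, the vascular call followed the raw STREP count of a cell. The lowest STREP count of a vascular cell was 14, 45, 87 and 270 in mice 1 to 4, and in mice 2 to 4 no intratissue cell had more. Of all cells, 37.8%, 39.4%, 30.3% and 22.9% lay within 1.5-fold of that value. Median STREP counts per cell were 10, 48, 130 and 471 in mice 1 to 4. Vascular shares rose in the same order, at 33.9%, 54.6%, 67.4% and 68.6%. Whether the spread of these shares comes from the STREP depth was not tested. ILC2 were vascular in 0 of 14, 1 of 7, 0 of 5 and 0 of 19 cells of mice 1 to 4, and AM at 23.0% ± 3.46 (SD, n = 4). With the label set on STREP per antibody count, by a common cut for all types of a mouse, the vascular share was 2.22% ± 2.31 in AM. It was 12.2% ± 8.24 in Mph against 35.4% ± 10.8 with the deposited label, and 85.0% ± 5.75 in NK cells against 52.3% ± 18.1. That label was not analysed in the other groups, so how the comparison with ORTHO-T would change is open.

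**Figure D4:**
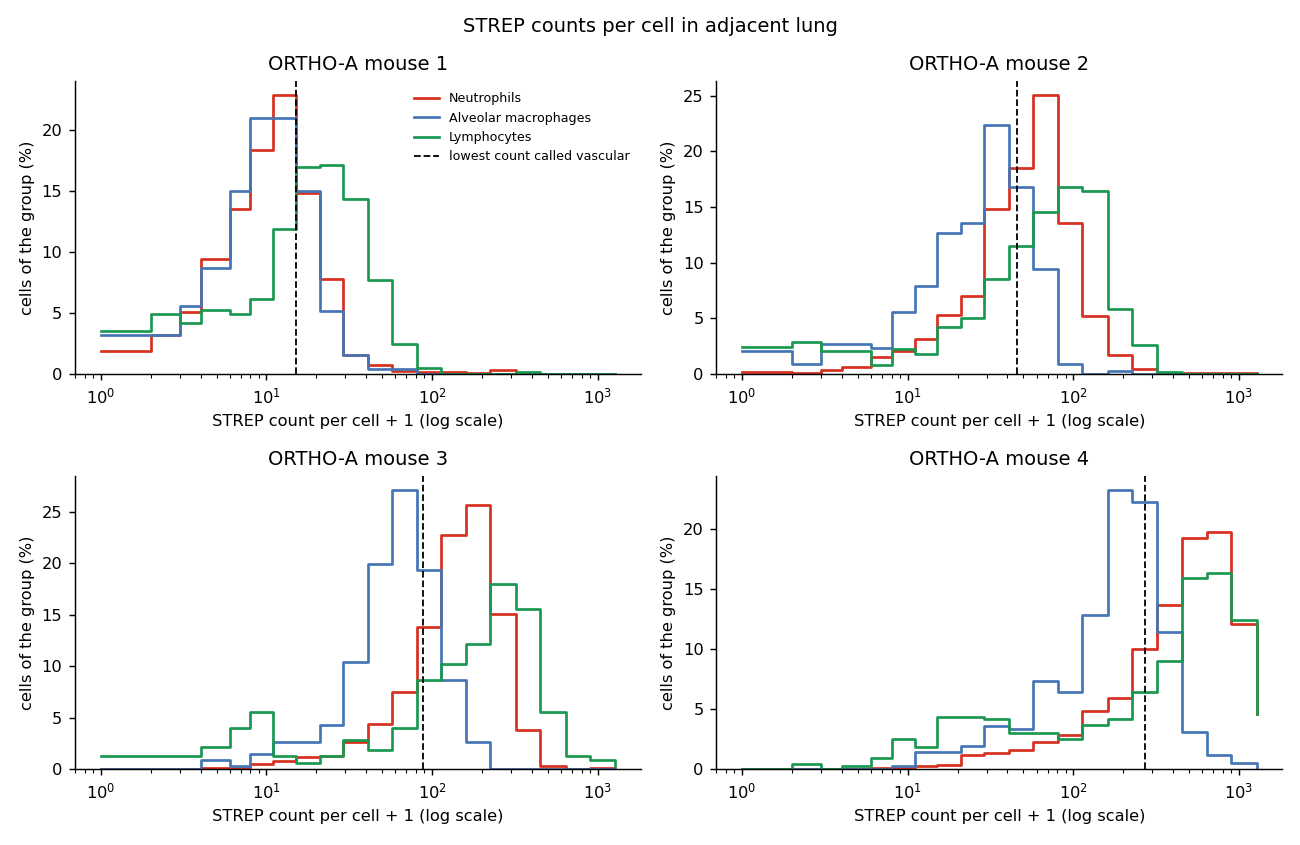
Percent of cells by STREP count, on a log axis of the count plus 1, for neutrophils, alveolar macrophages and lymphocytes of each ORTHO-A mouse, where the dashed line marks the lowest count called vascular and the last bin holds all higher counts. The lines of a mouse cross the dashed line without a gap there, at 14, 45, 87 and 270 counts.

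Vascular and intratissue neutrophils of ORTHO-A were compared to ask what differs between cells in the vessels and in the tissue of the same lung. Transcripts of 2 chemokines were lower in vascular neutrophils. Ccl3, which attracts monocytes and other leukocytes, stood at 31.0 ± 17.5 CPM against 78.4 ± 48.2 in the tissue (SD, n = 4 mice, log2 -1.38, SE 0.13, edgeR adjusted p 1.08e-07). Cxcl3, a neutrophil attractant, stood at 32.7 ± 29.1 against 80.1 ± 73.4 CPM (log2 -1.33, SE 0.16, adjusted p 0.00024). Both were lower in 4 of 4 mice. Higher in vascular neutrophils was Stfa3, a stefin A cysteine protease inhibitor, at 51.8 ± 31.6 against 26.6 ± 11.0 CPM (log2 0.99, SE 0.19, adjusted p 0.0152).

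In all, 21 of 6528 genes differed in neutrophils, 5 higher and 16 lower in the 4534 vascular cells against the 2785 intratissue cells, and 433 had an unadjusted p under 0.05. The other 4 higher genes were mitochondrial, mt-Nd1 (log2 0.65), mt-Co3 (0.33), mt-Co2 (0.30) and mt-Co1 (0.26), each higher in 4 of 4 mice. Clec4n, a C-type lectin receptor (log2 -0.59), and Ccrl2, a chemokine-binding receptor (-0.38), were lower. So were Zc3h7a (-0.64), AY036118 (-0.53), Filip1l (-0.52), Il1rapl1 (-0.44) and Jarid2 (-0.39). Bhlhe40 fell by 0.78 on the log2 scale, below the level asked of a named gene. Gm42418, the called gene with the most counts, made up 4.14% of neutrophil UMIs and 22.8% of UMIs in empty droplets.

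These genes lie, in GRCm38 coordinates, at chromosome 11, 83647843 to 83649378 (Ccl3), chromosome 5, 90786101 to 90788093 (Cxcl3), chromosome 16, 36450537 to 36455392 (Stfa3), chromosome 6, 123229843 to 123247024 (Clec4n) and chromosome 9, 111054834 to 111057518 (Ccrl2). Zc3h7a lies at chromosome 16, 11136594 to 11176393, Filip1l at chromosome 16, 57353277 to 57572804, Jarid2 at chromosome 13, 44730774 to 44921643, and Il1rapl1 at chromosome X, 86740937 to 88115948. AY036118, annotated as a long noncoding RNA, lies at chromosome 17, 39848112 to 39898385. It made up 2.63% of UMIs in empty droplets and 0.355% of neutrophil UMIs. Ccl3 lies near the related gene Ccl4, and Stfa3 belongs to a cluster of similar stefin A genes, so how counts were split between such neighbours is uncertain. The vascular label was also set on STREP per antibody count, with the number of vascular cells of each mouse and type kept. With it, 4 of the 21 genes kept their call, Ccl3, Cxcl3, Clec4n and Ccrl2, and the 21 changes had a median of 0.281 times their size. Among those that lost it, mt-Nd1 went to -0.05 (SE 0.14 before and 0.23 after), mt-Co3 to 0.07 (0.07 and 0.08), AY036118 to -0.01 (0.05 and 0.05), Zc3h7a to -0.11 (0.08 and 0.06), Filip1l to -0.06 (0.06 and 0.05), Jarid2 to -0.02 (0.08 and 0.07) and Il1rapl1 to 0.02 (0.10 and 0.10), so these calls ended with the change itself. Stfa3 stood at 1.30 (SE 0.19 and 0.58, adjusted p 0.695), so its call ended by a wider spread. Bhlhe40 at -0.60 (SE 0.17 and 0.17, adjusted p 0.108), mt-Co1 at 0.21 (0.05 and 0.06, 0.216) and mt-Co2 at 0.18 (0.06 and 0.06, 0.333) lost theirs by a smaller change at a similar SE. DESeq2 called 13 genes, and leaving out 1 mouse gave from 7 to 32.

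By gene list, 2 of 14 measured inflammatory cytokine and chemokine genes fell in vascular neutrophils, Ccl3 and Cxcl3, and 5 adjusted over the list alone. Il1rn stood at log2 -0.33 (adjusted p 0.0534), Il1b at -0.16 (0.122) and Cxcl2 at -0.17 (0.328), none past the test over all genes. The list as a whole did not pass fry (adjusted p 0.322) or camera (adjusted p 0.522 with an estimated correlation). In the list of the tumour-associated neutrophil state 1 of 12 fell, Ccl3, and 3 adjusted over the list alone, while Siglecf stood at -0.42 (adjusted p 0.6) and Cxcr4 at -0.10 (0.889). In the tissue residency list 1 of 9 fell, Bhlhe40. In the list of granule and maturity genes 0 of 14 passed over all genes by edgeR and 1 was higher adjusted over the list alone, with S100a8 at 0.19 (adjusted p 0.65), S100a9 at 0.12 (0.328) and Cxcr2 at 0.01 (0.991). With STREP per antibody count, 2 of these 14 were higher over all genes. In that setting 3 of 12 were lower in the list of the tumour-associated state and 0 of 9 in the residency list. Of 19 lists tested in neutrophils, 0 passed fry or camera with an estimated correlation after adjustment. Of these lists, 2 had an unadjusted fry p under 0.05, those of non-classical monocytes and MHC class II presentation.

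**Figure D5:**
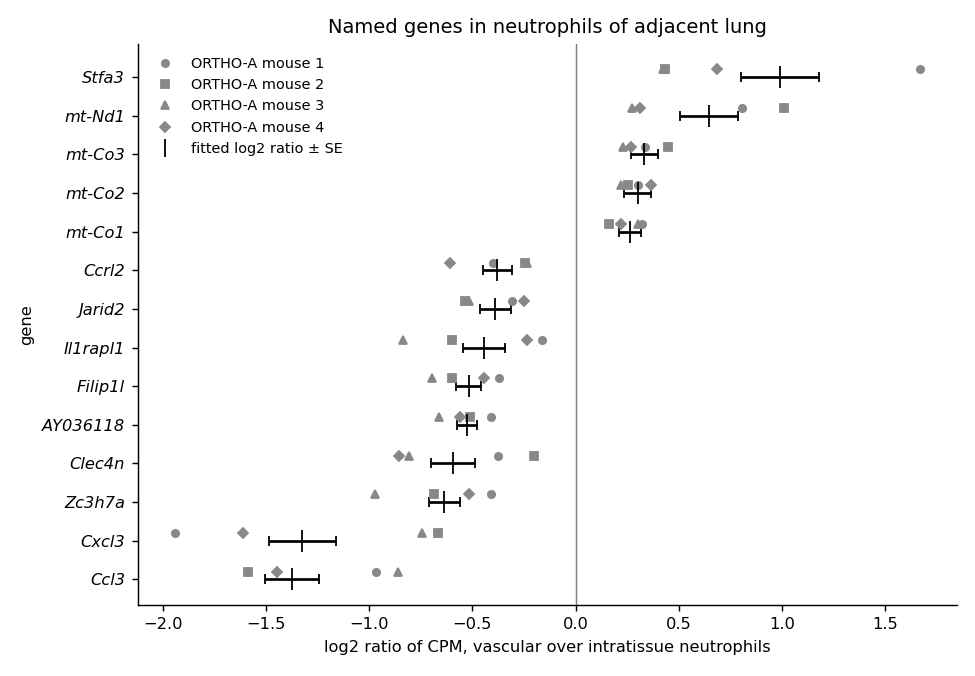
Log2 CPM change, vascular minus intratissue, of the named genes in ORTHO-A neutrophils, with a point per mouse and the edgeR estimate with its standard error. Ccl3 and Cxcl3 lie at -1.38 and -1.33 and the mitochondrial genes between 0.26 and 0.65.

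In AM, 2 of 6898 genes differed and 380 had an unadjusted p under 0.05. Pltp, a phospholipid transfer protein, rose by 0.73 on the log2 scale in the 317 vascular AM, at 198 ± 53.8 against 121 ± 20.2 CPM (SE 0.12, edgeR adjusted p 0.00638, chromosome 2, 164839518 to 164857708). Without mouse 3 or without mouse 4, 0 genes passed in AM, and another split of the AM sums within mice gave 21 genes. In B cells 3 of 2206 differed and 165 had an unadjusted p under 0.05. Pcmtd1 was higher (log2 1.38, SE 0.30, adjusted p 0.0292, chromosome 1, 7087077 to 7173628) and Zc3h7a lower (-1.06, SE 0.18, adjusted p 0.0112). Zc3h7a made up 0.364% of UMIs in empty droplets and 0.108% in annotated cells. Free RNA may thus add to its change, which was not tested in B cells. With STREP per antibody count, again at the same number of vascular cells per mouse and type, 0 of the 2 AM calls and 0 of the 3 B cell calls were kept. Pltp stood at 0.27 (edgeR adjusted p 0.895), Pcmtd1 at 0.44 (0.679) and Zc3h7a at -0.38 (0.837). The other B cell gene was the immunoglobulin segment Igkv19-93, named after its values were seen, with 217 ± 98.2 CPM in vascular and 0 in intratissue B cells. In NK cells 0 of 1601 genes passed in edgeR and 0 in DESeq2, and 97 had an unadjusted p under 0.05 in edgeR. No list passed fry or camera with an estimated correlation in these types. The lowest adjusted fry p was 0.125 in AM, 0.181 in NK cells and 0.29 in B cells. By fry's test for change in either direction, the residency list in AM (adjusted p 0.0422) and the cytotoxic effectors in NK cells (0.0217) passed, but not by camera with an estimated correlation (adjusted p 0.561 and 0.415). Over all genes, 0 of 6 residency genes passed in AM, with Rgs1 at -0.63 (adjusted p 0.913) and Itga1 at 0.75 (0.901), and 0 of 10 effectors in NK cells, with Gzma at 0.33 (0.15) and Gzmb at 0.48 (0.173).

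Surface proteins differed little between compartments of ORTHO-A. On vascular neutrophils, CD43 (log2 0.19, edgeR adjusted p 0.0457), CD48 (0.16, 0.0163) and CD172a (SIRPa) (0.13, 0.0457) were higher and CD54, the adhesion molecule ICAM-1, was lower (-0.16, 0.0457), each in 4 of 4 mice. These were the 4 of 186 antibodies that passed, and CD48 and CD54 were not above the highest isotype control. On vascular NK cells, Ly49D was higher (0.61, adjusted p 3.03e-05) and CD61, a platelet integrin chain, was lower (-0.52, 0.00495), each in 4 of 4 mice. Integrin b7, named after its values were seen, was also called there (0.52, 0.00495), in 3 of 4 mice. On vascular B cells, Integrin b7 (0.55, adjusted p 0.0451), CD79b of the B cell receptor (0.54, 0.0267) and CD49d (0.51, 0.0451) were higher, CD49d at a level not above the highest isotype control. With STREP per antibody count, CD43, CD48 and CD172a (SIRPa) kept their calls on neutrophils, CD54 did not (-0.19 with SE 0.07 in place of -0.16 with SE 0.03, adjusted p 0.213), and 0 of 3 calls were kept on NK cells and 0 of 3 on B cells. Ly49D on NK cells went to 0.15 (SE 0.11 before and 0.15 after, adjusted p 0.991), CD61 to -0.37 (0.13 and 0.14, 0.265) and Integrin b7 to 0.34 (0.13 and 0.14, 0.392). On B cells, CD79b stayed near its change, at 0.47 (SE 0.10 before and 0.10 after, adjusted p 0.0578), while Integrin b7 went to 0.33 (0.13 and 0.11, 0.377) and CD49d to 0.28 (0.12 and 0.10, 0.377). Without TMM, CD54 alone passed on neutrophils (-0.22), with CD43, CD48 and CD172a (SIRPa) at 0.13, 0.10 and 0.07. On B cells 0 antibodies passed, with Integrin b7, CD79b and CD49d at 0.46, 0.45 and 0.41, and on NK cells 3 passed, 1 higher and 2 lower, without Integrin b7 (0.39, adjusted p 0.129). Without mouse 3 or without mouse 4, 0 antibodies passed on neutrophils, and without mouse 4, 0 on B cells. On AM, 0 antibodies passed in edgeR and 10 had an unadjusted p under 0.05. Per cell, isotype controls were 1.49-fold, 1.66-fold, 1.20-fold and 1.40-fold higher in vascular neutrophils, AM, NK cells and B cells, and all other antibodies 1.57-fold, 1.60-fold, 1.40-fold and 1.43-fold.

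The cultured LLC-Thy1.1 lines were compared for cells annotated Ly6a+, named for the surface antigen Sca-1. In P0, 4 of 2472 cells carried that name, 0.162% with an exact 95% interval of 0.0441% to 0.414%. In P2, 983 of 3470 did, 28.3% with an interval of 26.8% to 29.9%. There was 1 culture per passage, so this compares those cultures and has no replicate check.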

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

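The values here were picked by a fixed rule for a mouse standing apart from the other 3 of its group, and the test on doublet scores of NeuMono was chosen only after the result was seen. Of 156 groups of 4 mice tested, 14 had such a mouse, and chance alone gives about 5% of groups. In 4 of them the other 3 mice were at 0, where any cell at all sets a mouse apart, and without those 10 of 152 groups had such a mouse.

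NeuMono, a type whose name joins neutrophil and monocyte, made up 2.77% of ORTHO-A cells in mouse 4 against 0.578% to 0.872% in the other mice, and 1.94% in ORTHO-T mouse 4 against 0.551% to 0.649%. Doublets of a neutrophil and a monocyte are a candidate explanation, since 92.5% of NeuMono cells had a doublet score above 0.5. The median UMIs of NeuMono were 0.842, 0.502, 0.628 and 0.679 of the summed medians of neutrophils and classical monocytes in mice 1 to 4 of ORTHO-A, where a pair of whole cells would give about 1. The same ratios of antibody counts were 1.06, 0.982, 0.917 and 0.931. The ratios took classical monocytes as the only partner, so a UMI ratio under 1 does not speak against doublets with another cell. In ORTHO-A mouse 4, which held 126 of the NeuMono cells, Non-class Mono were more common than Class Mono, at 11.2% against 4.80%. Pairs with Non-class Mono were not tested. Whether NeuMono may be doublets or a separate state thus stays open.

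Class Mono made up 4.80% of ORTHO-A cells in mouse 4 against 2.45% to 2.64%, and 4.43% of ORTHO-M cells in mouse 2 against 1.39% to 1.85%. Non-class Mono made up 11.2% of ORTHO-A cells in mouse 4 against 1.37% to 1.74%, and 3.31% of ORTHO-T cells in mouse 4 against 0.324% to 0.669%. Treg made up 0.0881% of ORTHO-A cells in mouse 4 against 0.234% to 0.249%. The cDC1 share of ORTHO-T mouse 2 was 0.826% against 0.574% to 0.602%. B cells made up 0.738% of SUBCUT cells in mouse 4 against 0.179% to 0.249%.

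Among vascular shares, Other T of ORTHO-A mouse 3 stood at 36.4% against 13.6% to 16%. In SUBCUT mouse 3, 2.70% of NK cells, 9.09% of Other T, 5.56% of Treg and 5.88% of cDC2 were called vascular, against 0% in each other mouse. These are 1, 2, 1 and 1 cells, so they set no mouse apart.

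Among finer subtypes, 10 of 60 had a share in every ORTHO-A mouse above every ORTHO-M mouse, and 28 of 66 did so in ORTHO-T.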

How the results depend on the processing

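Of 61 called differences between cell types, 30 stayed called the same way in every setting. Of 893 values, 820 stayed, 72 no longer passed and 1 turned. For named genes and antibodies, 0 of 27 stayed in every setting, with 179 of 296 values kept, 115 no longer past the test and 2 turned. The settings without neutrophils, without NeuMono and DC3, with a doublet score under 0.5, and with STREP per antibody count were chosen only after the result was seen. Apart from the explanations weighed at the end, the cause of a changed result was not tested.

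For ORTHO-A against ORTHO-M, 17 types became 5 with TMM factors on the cell counts, 10 among extravascular cells and 4 without neutrophils. NK cells in ORTHO-T against ORTHO-A turned to a log2 ratio of -0.0522 without neutrophils. Prolif NK/T in ORTHO-T against ORTHO-M turned from -0.232 (adjusted p 0.641) to 1.52 among extravascular cells (0.0128). Leaving out 1 mouse gave 15 to 17 types for ORTHO-A against ORTHO-M, 14 to 17 for ORTHO-T against ORTHO-A, 11 to 13 for ORTHO-T against ORTHO-M and 16 to 18 for SUBCUT against ORTHO-T.

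With mouse number as a block, ORTHO-T against ORTHO-A gave 18 types with all 15 calls kept, and the difference in vascular share stayed at -39.2 with an exact p of 0.125, the smallest possible with that pairing. Numbers 1 and 4 correlated best with their own number between tumour and adjacent lung and 2 and 3 did not, so the pairing is uncertain. Leaving out 1 mouse gave differences from -46.6 (without ORTHO-A mouse 1) to -35.1 (without ORTHO-A mouse 4), with an exact p of 0.0571 without any ORTHO-T mouse. The same ranges were -0.737 to 10.8 for ORTHO-A against ORTHO-M and -17.0 to -13.0 for SUBCUT against ORTHO-T.

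In neutrophils, 21 genes became 13 with DESeq2, 0 without the block and 56 with the middle of the STREP counts left out. The 4 antibodies became 1 without TMM, 0 without the block, 11 with a doublet score under 0.5 and 10 with STREP per antibody count. In AM, 2 genes became 1 with DESeq2, 17 with every gene, 1 without the block and 1 with STREP per antibody count, where 0 of the 2 were kept. In NK cells, 0 genes became 4 with every gene, 4 with equal cells and totals and 3 with STREP per antibody count, and 3 antibodies became 0 without the block and 1 with STREP per antibody count, where 0 of the 3 were kept. In B cells, 3 genes became 22 with every gene, 1 without the block, 14 with equal cells and totals, 29 with the middle of the STREP counts left out and 1 with STREP per antibody count, where 0 of the 3 were kept. The 3 antibodies on B cells became 0 without TMM, 0 without the block and 0 with STREP per antibody count, with changes at a median of 0.823, 1.03 and 0.599 times their size. With STREP per antibody count, mt-Nd1 (-0.0543) and Il1rapl1 (0.0151) turned in neutrophils.

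Leaving out 1 mouse gave 7 to 32 genes in neutrophils, with 32, 8, 15 and 7 without mice 1 to 4. The same was 0 to 14 in AM (14, 2, 0 and 0), 1 to 1 in NK cells, and 4 to 14 in B cells (12, 9, 14 and 4). For antibodies it was 0 to 13 on neutrophils (13, 7, 0 and 0), 0 on AM, 2 to 3 on NK cells and 0 to 10 on B cells (10, 4, 3 and 0). Camera with an estimated correlation called 0 lists in each type. With a preset correlation instead, some lists passed, such as the inflammatory list in neutrophils (camera adjusted p 5.78e-13). That setting leaves aside the correlation between genes in these data, estimated at 0.234 for that list. Ly6a+ shares with a doublet score under 0.5 were 0.166% in P0 and 28.5% in P2. The stricter STREP call was not run for AM, where 1 mouse was left, and agreement of CMO and HTO labels was not used here.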

Other observations

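Finer annotations divide each type, and their shares, chosen here after the values were seen, are percentages of all cells of that annotation in a mouse (mean ± SD, n = 4). CD62L+ Neutro made up 97.4% ± 1.5 of neutrophils in ORTHO-M, 96.7% ± 0.598 in ORTHO-A, 49.6% ± 7.78 in ORTHO-T and 0 of 5419 in SUBCUT, which allows up to 0.0554%. CD62L, or L-selectin, is shed by activated neutrophils. In ORTHO-T, 21.9% ± 6.80 were Clec4n+ Neutro against 0.569% in ORTHO-A (exact permutation p = 0.0286, adjusted p 0.04), and Mif+ Neutro reached 21.1% ± 2.57 in ORTHO-T and 50.1% ± 9.27 in SUBCUT. Pglyrp1+ Neutro made up 38.1% ± 6.92 in SUBCUT and 0 of 3120 in ORTHO-T (up to 0.0962%), and Clec4n+ Neutro 0 of 5419 in SUBCUT. Among monocytes and macrophages together, Lipid TAM made up 46.5% ± 7.23 in ORTHO-T against 6.14% ± 5.73 in ORTHO-A (adjusted p 0.0444 of the exact permutation test), while the subtypes named TAM, Folr2+ TAM and Hypoxic TAM made up 25.5% ± 2.93, 20.1% ± 5.45 and 20.2% ± 2.89 in SUBCUT. Lipid TAM were 0 of 7016 in SUBCUT (up to 0.0428%) and TAM 0 of 6086 in ORTHO-T (up to 0.0493%). Each tumour group also had its own annotation. For monocytes and macrophages, 11 of 11 names in SUBCUT and 11 of 11 in ORTHO-T each lay within 1 shared name. For neutrophils this held for 3 of 10 names in SUBCUT and 3 of 9 in ORTHO-T. Such zeros on either side may thus come from how clusters of the different tumours were named, which these counts cannot decide. The upper limits cover counting error only.

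Among T, NK and innate lymphoid cells together, Mature NK made up 26.7% in ORTHO-A and 3.41% ± 1.58 in ORTHO-T (exact permutation test, adjusted p 0.0476). Immature NK_1 stood at 28.3% ± 9.83 in ORTHO-T, and Immature NK_2 at 32.1% ± 8.76 in SUBCUT against 1.42% in ORTHO-T. Exhausted T made up 1.25% in ORTHO-A, 9.20% ± 2.05 in ORTHO-T (0.0476 against ORTHO-A) and 17.0% ± 2.37 in SUBCUT (0.0429 against ORTHO-T), all by adjusted exact permutation p. Treg made up 15.1% ± 1.55 of that annotation in SUBCUT and 3.91% in ORTHO-T. JunB+ B made up 51.9% ± 5.87 of B cells in ORTHO-T and 6.54% in ORTHO-A (exact permutation test, adjusted p 0.0429).

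Of the explanations weighed next, the free RNA tests, the test on inflammatory genes, the splits of cell counts and the limit to splits within mice were chosen only after the result was seen, as was the label on STREP per antibody count. RNA differences between vascular and intratissue neutrophils may in part come from the label, because with STREP per antibody count 19.0% of the 21 called genes kept their call and the changes had a median of 0.281 times their size. Free RNA could add to it, since genes lower in vascular cells had a median share in empty droplets 4.27 times that in neutrophils, but genes called higher also stood at 2.48. That median does not hold for the genes that kept their call, Ccl3 (0.685), Cxcl3 (0.295), Ccrl2 (0.347) and Clec4n (1.25). Among those whose change went away were AY036118 (7.40), Zc3h7a (7.25), Jarid2 (7.35), Il1rapl1 (9.37) and Filip1l (4.32). Against doublets, 71.4% of calls were kept with a doublet score under 0.5. Changes with equal cells and totals were 1.02 times those with all cells. Drawing cells and counts at random leaves the expected share of each gene as it was, so this cannot decide on unequal RNA per cell. For the inflammatory list, 6 of 14 genes were lower with STREP per antibody count, against 2 with the deposited label, among them Ccl3 (-1.49), Cxcl3 (-1.27) and Il1rn (-0.43). The fall of these genes thus did not hang on the threshold on the raw STREP count. Whether depth differed between compartments under the other label was not tested, so depth is not excluded. Stfa3 (1.30), mt-Co1 (0.21), mt-Co2 (0.18) and Bhlhe40 (-0.60) lost their call with most of their change left, and what lowers other genes, such as AY036118, stays open.

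AM reside in the airspaces, yet 23.0% of them were called vascular in ORTHO-A. Antibody background is a candidate explanation. With a common cut per mouse on STREP per antibody count, the share was at most 0.246 of the deposited one in any mouse. But median antibody counts per mouse were 4269 to 5104 in AM against 2803 to 3181 over all cells. Dividing by them lowers the AM share whether or not their STREP counts are background, so this cannot decide on background. The share at a doublet score under 0.5 was at least 0.972 of that of all AM. Over all groups, only 3.07% of AM scored above 0.5, so leaving them out could hardly move the share. This cannot decide on doublets with a vascular cell. Whether blood reached some airspaces stays open.

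Relabelling all splits of the mice asks whether chance can be excluded. For the number of cell types called, 1 of 35 splits, the real one, gave as many calls, a share under 5%. The calls were 15 against a highest other of 4 for ORTHO-T and ORTHO-A, and 17 against 2 for ORTHO-A and ORTHO-M. They were 12 against 0 for ORTHO-T and ORTHO-M, and 17 against 3 for SUBCUT and ORTHO-T. This makes chance unlikely for these counts, but it covers no single type and cannot part group from capture. If ORTHO-T and ORTHO-A are paired by mouse, which is uncertain, too few splits remain for a share under 5%. Within ORTHO-A both compartments come from the same mice, so the pairing leaves 8 splits within mice, too few for a share under 5%. The real counts and the highest of the other splits were 21 and 2 for neutrophil RNA and 4 and 0 for neutrophil antibodies, with 1 of 8 splits as large in each. They were 2 and 21 for AM RNA (2 of 8 splits), 0 and 0 for AM antibodies (8 of 8), 0 and 1 for NK RNA (8 of 8) and 3 and 1 for NK antibodies (1 of 8). For B cells they were 3 and 2 for RNA (1 of 8) and 3 and 3 for antibodies (2 of 8). The split of AM sums with 21 genes, several times the real count, points to a structure of the samples that was not tested.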
